A study of Mus musculus and Rattus norvegicus with 24 samples.

How the data were processed

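The series held 24 RNA-seq samples. Of these, 18 were mouse hearts in 6 groups of 3 libraries, named by genotype (ctrl or cKO, read from the sample titles and the design text as control and conditional knockout of ATF4) and by surgery: sham, or transverse aortic constriction (TAC), a band on the aorta that loads the left ventricle, for 3 or 7 days. The other 6 were neonatal rat ventricular myocytes (NRVM), heart muscle cells cultured from newborn rats, treated with an adenovirus carrying GFP (adGFP, 3 libraries) or ATF4 (adATF4, 3 libraries). One characteristic of the mouse samples is headed overexpression, which goes against the titles and the design text; the groups were taken from the titles. Whether replicates came from separate animals or cultures is not stated in the labels, so the p-values measure the spread between these samples, part of which may be technical.

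For the mouse hearts the authors deposited whole-number read counts per Ensembl gene with no normalization. The submitters' processing notes list Bowtie 0.12.2 and the build mm9 with no role; the counting tool and its strand setting are not given in the sources used here. The deposited gene positions were those of GRCm38: 53585 of the 54495 gene IDs found in GENCODE M21 had the same chromosome, start and end there. Positions below are GRCm38 positions from the deposited table. The same table held the authors' own log2 fold changes and adjusted p-values for 5 comparisons, deposited with no statement of the test; they are quoted only where the authors' deposited table is named. Per the file headers the table also gave a length for each gene. For the rat cells the authors deposited FPKM values per gene symbol; the same processing notes list mm9 for these rat samples too, and the quantifier and annotation are not given in the sources used here. Among the rat gene names, 26 were calendar dates, as spreadsheet programs make of some gene symbols; they were left out. A further 6 columns of per-sample values beside the rat data matched no sample of the series and were not used.

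Mouse library totals ran from 15106975 to 18112798 counts. Total reads of the rat libraries were not given. Ratios between the low FPKM values of single genes fell on small whole-number ratios within 0.01 log2 units for 89.3% to 93.3% of the genes compared, which put the depth of the other rat libraries at 0.920 to 1.32 times that of adGFP replicate 1. No libraries of a group were identical: the chi-square per degree of freedom between mouse libraries of a group was 7.60 to 162. In the mouse table, 207 symbols were shared by more than one gene ID.

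Mouse counts were tested with edgeR 4.0.16 in R 4.3.3: genes with low counts were removed with filterByExpr, which left 15535 genes holding 99.9% of the counts; libraries were scaled by TMM; and 1 quasi-likelihood model with the 6 groups was fitted to all 18 libraries, so that the groups shared the estimate of the spread. Levels are given as TMM-scaled CPM, a count as a share of the scaled library total. Rat values were tested with limma 3.58.1 (empirical Bayes with a trend) on log2(FPKM + 1), for the 10571 genes with at least 1 FPKM in at least 3 libraries. A fold change there is on the log2(FPKM + 1) scale, which understates the change of low genes. The choice of edgeR for counts and limma for FPKM was also written before the data were examined. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene is said to be called, higher or lower, when its adjusted p is under 0.05. All tests were two-sided.

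The comparisons were cKO against ctrl in sham hearts, at TAC 3 d and at TAC 7 d; TAC 3 d and 7 d against sham within each genotype; the genotype by TAC interaction at each day, which compares the response to TAC between genotypes; and adATF4 against adGFP. A contrast of the genotype effect at 7 d with that at 3 d was added after seeing the data. Before the data were examined, 36 gene lists holding 586 genes were fixed, covering ATF4 pathways, metabolism, stress responses, cardiac function and markers of the cell types of the heart. Each was tested against the other genes with camera, with the preset correlation of 0.01 and again with an estimated correlation, and members called were counted with the p-values adjusted over all genes and adjusted over the list alone. No list was called with an estimated correlation in any comparison. Genes called at least 2-fold higher or lower in the rat cells were also tested as sets in the mouse hearts, joined by symbol.

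Genes named in the text follow a rule written before the data were examined: Atf4 always; the 6 largest rises and the 6 largest falls among called genes with a mean of at least 1 log2 CPM, or 1 FPKM, and groups that do not overlap (for interactions without the last condition), passing over unnamed gene models; and from each list up to 3 called members with the smallest adjusted p. The rule names up to 109 genes in a comparison; the text reports a part of these, picked after their values were seen, and leaves out some of the largest rises and falls. Genes named outside this rule are said to have been chosen after their values were seen. Fold changes are given with a standard error (SE), and levels as mean ± SD of 3 libraries. For the rat cells the SE is that of the limma model. For the mouse hearts it is the absolute log2 fold change over the square root of the F value of the test. The mouse SE thus follows from the test and is no separate measure of precision.

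The model steps were tested on simulated data with 200 genes changed by a known fold. The changed genes were drawn from those with a mean of at least 1 log2 CPM. In the rat data the mean of log2(FPKM + 1) was at least 2. The shares recovered thus do not cover low genes. For cKO against ctrl at TAC 7 d, edgeR recovered 82.1% of the genes changed 2-fold and 92.4% of those changed 4-fold, with 10 false calls among 15287 genes. There DESeq2 recovered 86.6% and 95.5%, with 30 false calls among 15535 genes. DESeq2 was simulated in this comparison alone. For the genotype by TAC 3 d interaction edgeR recovered 49.3% and 81.8%. For adATF4 against adGFP, limma recovered 100% of the genes changed 2-fold. Alternatives tried were the size factors of DESeq2 1.42.0 within edgeR and the DESeq2 Wald test, no filter on low values, a fold threshold of 1.5, the replicate number as a block, a fit on the libraries of the groups compared alone, a pseudocount of 0.1, limma without trend, median-centred log values, rat sets with no fold limit, and each library left out in turn. Library sizes with no scaling factor, the removal of libraries that stood apart, and offsets that remove the trend of each library with gene length (a smooth curve over log length) were added after seeing the data. Summaries and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.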

Results

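RNA was sequenced from 18 mouse hearts and from 6 cultures of neonatal rat ventricular myocytes (NRVM). The hearts fell into 6 groups of 3: ctrl and cKO, each after sham surgery and after 3 or 7 days of transverse aortic constriction (TAC). The rat cells carried adenovirus for GFP (adGFP, n = 3) or ATF4 (adATF4, n = 3). ATF4 is a transcription factor that raises genes of amino acid supply when protein synthesis is stressed. Mouse libraries held 15106975 to 18112798 counts. On the first principal component of the hearts, which held 39.6% of the variance, the library of ctrl TAC 3 d replicate 3 lay apart at 87.7; its mitochondrial share was 10.6%, against 14.5% to 23.0% in the other 17. The library of cKO TAC 3 d replicate 2 lay at -55.8 on the second component, which held 11.4%, and that of cKO TAC 7 d replicate 2 at 54.5 on the first and -36.8 on the second. Counts of genes that depend on these libraries are given with and without them. Log levels relative to the mean of all libraries followed gene length to differing degrees: the Spearman correlation was -0.15 to 0.01 in the 6 sham libraries, -0.30 to 0.01 in the 6 of TAC 3 d and 0.10 to 0.25 in the 6 of TAC 7 d.

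Atf4 RNA (ENSMUSG00000042406, chromosome 15, 80255184 to 80257541, plus strand) was lower in cKO than in ctrl hearts in each condition. In sham hearts it was 23.5 ± 2.66 CPM in cKO and 56.5 ± 19.2 CPM in ctrl (SD, n = 3 each; log2 fold change -1.26 ± 0.18 SE, adjusted p = 0.0487). At TAC 3 d it was 25.6 ± 1.32 against 85.4 ± 5.39 CPM (-1.74 ± 0.19, adjusted p = 0.000334), and at TAC 7 d 28.5 ± 2.43 against 73.6 ± 5.50 CPM (-1.37 ± 0.18, adjusted p = 0.00423). The highest cKO library stood at 31.3 CPM and the lowest ctrl library at 34.3 CPM (in raw counts the highest cKO library held 536 and the lowest ctrl library 531). The wide spread in ctrl sham came from the library labelled ctrl sham replicate 3, at 34.3 CPM beside 66.2 and 68.8 CPM, and without it the sham difference was -1.52 ± 0.11 (adjusted p = 6.15e-06). The sham call was lost without any other single sham library, with the highest adjusted p, 0.249, without ctrl sham replicate 2. In rat myocytes Atf4 rose from 276 ± 31.1 to 2563 ± 143 FPKM with adATF4 (3.21 ± 0.10, adjusted p = 1.25e-08).

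Of the genes beside Atf4 on the map, 2 differed between cKO and ctrl hearts. Rps19bp1, which lies next to Atf4 on the minus strand (80260615 to 80264315), was lower in cKO at TAC 3 d (-1.38 ± 0.28, adjusted p = 0.00512) and at TAC 7 d (-1.60 ± 0.29, adjusted p = 0.0318), and was not called in sham hearts (-1.09, adjusted p = 0.833). Cacna1i, a T-type calcium channel gene that starts 29.7 kb after Atf4 (80287238 to 80398279, plus strand), had 303 to 1500 counts in each of the 9 cKO libraries and 0 to 4 counts in 8 of the 9 ctrl libraries. Its adjusted p was 0.00231 at TAC 3 d and 0.0160 at TAC 7 d. The 7 d calls of both genes, though not the differences, were lost without some single libraries. The adjusted p of Cacna1i was 0.0625, 0.154 and 0.0993 without ctrl TAC 7 d replicates 1, 2 and 3. Without cKO TAC 7 d replicate 2 it was 0.0560. The adjusted p of Rps19bp1 was 0.0625, 0.154 and 0.119 without ctrl TAC 7 d replicates 1, 2 and 3. It was 0.168 and 0.0626 without cKO TAC 7 d replicates 2 and 3. With each library of these groups left out in turn, the log2 fold change was 8.82 to 10.7 for Cacna1i. For Rps19bp1 it was -1.88 to -1.44. The remaining ctrl library, labelled ctrl sham replicate 3, had 381 counts, and the sham difference was not called with it (adjusted p = 0.999) and was called without it (adjusted p = 5.31e-05). These neighbours were examined after their values were seen. In the rat cells Rps19bp1 was at -0.10 ± 0.15 (adjusted p = 0.613).

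**Figure D1:**
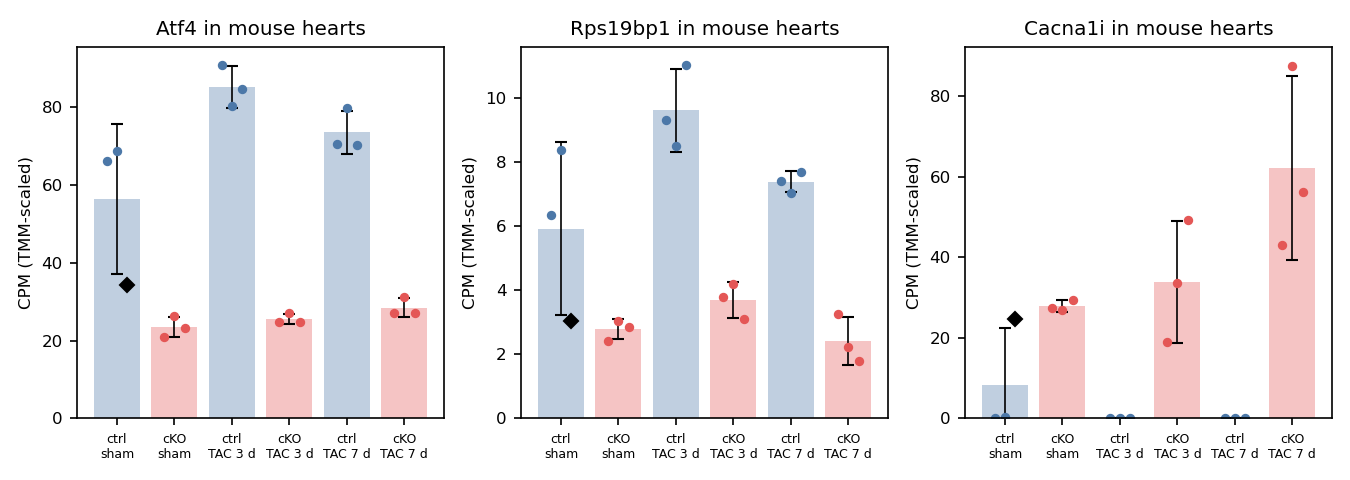
Levels of Atf4, Rps19bp1 and Cacna1i in TMM-scaled CPM (y axis) in the 6 groups (x axis) of mouse hearts; bars are means with SD of 3 libraries, points are libraries, and the black diamond is the library labelled ctrl sham replicate 3. Atf4 was at 25.6 CPM in cKO and 85.4 CPM in ctrl at TAC 3 d.

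**Figure D2:**
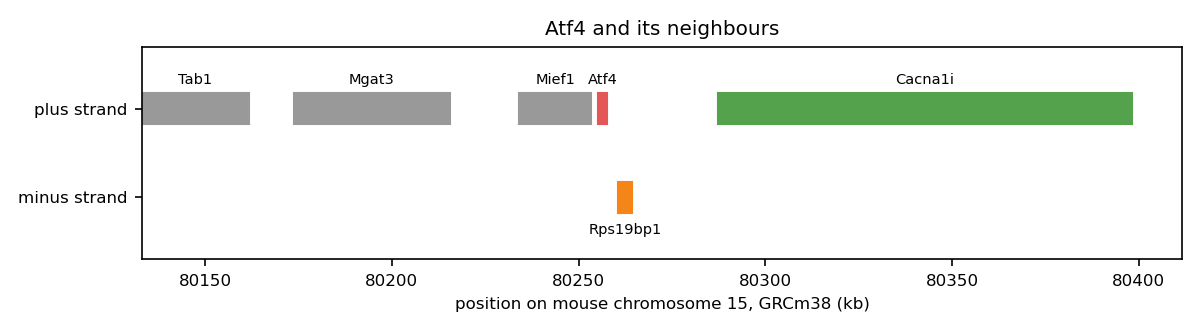
Map of mouse chromosome 15 around Atf4, with GRCm38 positions in kb on the x axis and genes on the plus and minus strands as boxes. Cacna1i starts 29.7 kb after the end of Atf4.

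**Figure D3:**
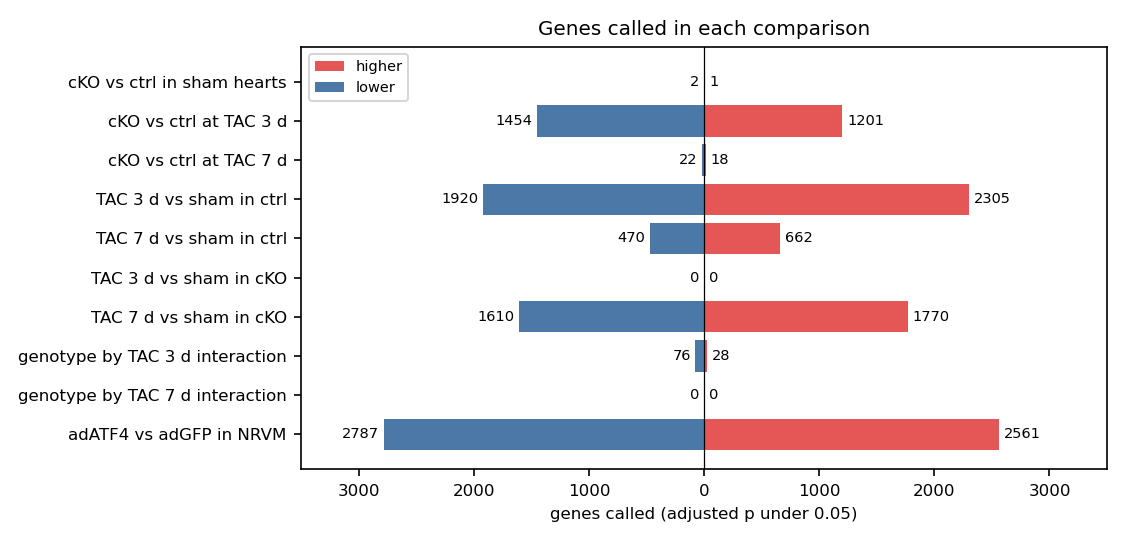
Bars give the number of genes called higher (red) and lower (blue) in each comparison, at an adjusted p under 0.05. Counts ran from 0 for TAC 3 d against sham in cKO to 5348 for adATF4 against adGFP.

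**Figure D4:**
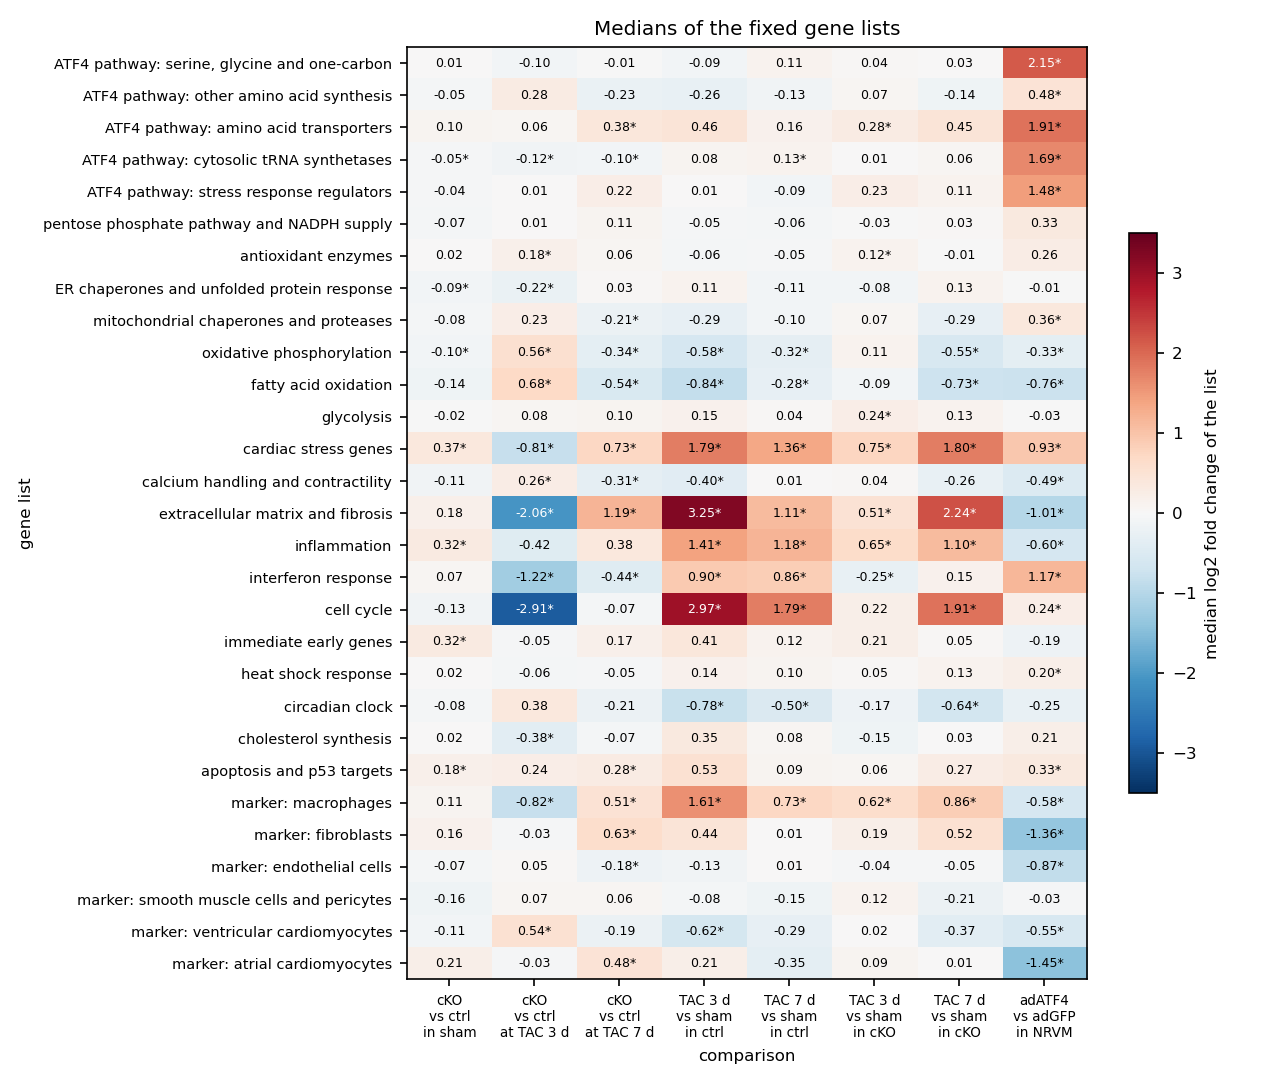
Median log2 fold change (colour) of the members of 29 gene lists (y axis) in 8 comparisons (x axis), with an asterisk where camera gave an adjusted p under 0.05 with the preset correlation. Cell cycle genes stood at -2.91 in cKO against ctrl at TAC 3 d.

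In unloaded (sham) hearts, edgeR called few genes between cKO and ctrl. On simulated data for this comparison it recovered 86.6% of the genes changed 2-fold and 92.4% of those changed 4-fold. Of those changed 1.5-fold it recovered 19.4%. A low count thus does not show that few genes differ. Klhdc7a, a kelch-domain gene, was higher in cKO (25.3 ± 3.39 against 7.84 ± 1.89 CPM; 1.69 ± 0.26, adjusted p = 0.0487). Dmd, which encodes dystrophin, was lower (51.1 ± 2.78 against 92.5 ± 1.37 CPM; -0.86 ± 0.14, adjusted p = 0.0487). With Atf4 these were the 3 genes called (1 higher, 2 lower) by edgeR. An unadjusted p under 0.05 was found for 565 genes. This is fewer than the share of 0.05 of the 15535 tested genes that no difference would give on average. The spread was shared with the TAC groups. Between libraries of a group the chi-square per degree of freedom was 7.60 to 19.7 in sham and 23.0 to 162 at TAC 3 d. The shared spread may thus make p-values in sham hearts too large, so the 565 do not show that no genes differ. DESeq2 called 16, and edgeR 67 with no filter on low counts and 31 on the sham libraries alone. None of the 3 kept its call with every library left out in turn, and without the library labelled ctrl sham replicate 3 those called were Atf4 and Cacna1i, with Klhdc7a at 1.60 (adjusted p = 0.310) and Dmd at -0.84 (adjusted p = 0.239). The authors' deposited table gave 99 genes with an adjusted p under 0.05 (59 higher, 40 lower).

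Of the 36 lists, 8 were called in sham hearts with the preset correlation, although no member of them was called over all genes. Targets of p53 and apoptosis genes had a median of 0.18 in cKO (0 higher, 0 lower, 16 not called; 3 higher adjusted over the list alone; adjusted p = 4.03e-05, and adjusted p = 0.0979 with an estimated correlation). Cardiac stress genes had a median of 0.37 (0 of 14 called, and 0 adjusted over the list alone; adjusted p = 0.00596, and adjusted p = 0.742 with an estimated correlation) and genes of oxidative phosphorylation -0.10 (0 of 30 called, and 0 adjusted over the list alone; adjusted p = 0.0324, and adjusted p = 0.803 with an estimated correlation). The number of lists called fell to 3 without cKO sham replicate 2.

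At TAC 3 d, cKO hearts had lower RNA of proliferation, matrix and macrophage genes and higher RNA of mitochondrial energy genes than ctrl hearts. edgeR called 2655 genes, 1201 higher and 1454 lower in cKO. Plk1 and Bub1b, which drive and check mitosis, were at 0.864 ± 0.294 against 7.91 ± 2.52 CPM (-3.16 ± 0.41, adjusted p = 0.000590) and at 1.44 ± 0.531 against 10.4 ± 3.14 CPM (-2.83 ± 0.37, adjusted p = 0.000590). Loxl2, a collagen cross-linking enzyme, was at 27.3 ± 4.93 against 103 ± 29.96 CPM (-1.92 ± 0.26, adjusted p = 0.000730). Ppara, the nuclear receptor that drives fatty acid oxidation genes, was at 22.8 ± 5.77 against 8.51 ± 0.942 CPM (1.42 ± 0.26, adjusted p = 0.00312). Without ctrl TAC 3 d replicate 3 the count was 1097 genes, without cKO TAC 3 d replicates 1 or 2 it was 1762 or 953, and it was 450 (115 higher, 335 lower) without ctrl TAC 3 d replicate 3 and cKO TAC 3 d replicate 2 together. A fit on the libraries of these 2 groups alone called 114 genes, and DESeq2 called 3168. The fit on these groups alone has fewer samples. The spread of the main model also draws on groups whose libraries differed less, so its p-values at TAC 3 d may be too small. The authors' deposited table gave 1227 genes, 382 higher and 845 lower.

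Of the cell cycle list, 25 of 25 members were lower in cKO at TAC 3 d (25 adjusted over the list alone; median -2.91, adjusted p = 3.60e-33, and adjusted p = 0.247 with an estimated correlation); without both libraries named above 23 were lower and the median was -2.63. Of the extracellular matrix and fibrosis list, 27 of 32 were lower and none was higher (29 lower adjusted over the list alone; median -2.06, adjusted p = 4.27e-21, and adjusted p = 0.386 with an estimated correlation); without both libraries 17 were lower and the median was -1.50. The basement membrane collagen Col4a1 was at 716 ± 125 against 1828 ± 397 CPM (-1.35 ± 0.19, adjusted p = 0.000774). The 6 largest falls named by the rule were smaller without ctrl TAC 3 d replicate 3, and 3 of them kept their call. The collagen genes Col8a2, Col9a2 and Col12a1 stood at -5.24, -4.03 and -3.91, and without that library at -2.28 (adjusted p = 0.0491), -2.54 (adjusted p = 0.0176) and -2.15 (adjusted p = 0.0310). Fmod, Serpinb1a and Ptn stood at -6.12, -5.72 and -4.93, and without it at -2.99 (adjusted p = 0.0576), -1.34 (adjusted p = 0.104) and -1.46 (adjusted p = 0.138).

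Macrophage markers were lower in cKO at TAC 3 d for 8 of 16 members, with 1 higher and 7 not called (12 lower and 1 higher adjusted over the list alone). The median was -0.82 (adjusted p = 8.17e-05, and adjusted p = 0.386 with an estimated correlation). Cx3cr1, a chemokine receptor of macrophages, was at 2.76 ± 1.11 against 19.9 ± 14.4 CPM (-2.83 ± 0.46, adjusted p = 0.00179). Interferon response genes were lower for 11 of 18, with 7 not called (17 lower adjusted over the list alone; median -1.22, adjusted p = 1.27e-09, and adjusted p = 0.386 with an estimated correlation); the interferon-induced gene Oasl2 was at 11.9 ± 2.54 against 32.3 ± 13.9 CPM (-1.44 ± 0.30, adjusted p = 0.00544). Without ctrl TAC 3 d replicate 3 and cKO TAC 3 d replicate 2, 1 macrophage marker and 0 interferon response genes were called lower by edgeR, with medians of -0.37 and -0.70. Without ctrl TAC 3 d replicate 3, cKO TAC 3 d replicate 2 or cKO TAC 3 d replicate 3 alone, 2, 3 or 3 macrophage markers were lower, and without the first or the second of these 4 interferon response genes each. Fibroblast markers went both ways: 3 were higher, 3 lower and 6 not called of 12 (3 and 3 adjusted over the list alone; median -0.03), among them Gsn, an actin-severing protein (1.38 ± 0.25, adjusted p = 0.00312).

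Energy genes were higher in cKO at TAC 3 d. Of the oxidative phosphorylation list 18 of 30 were higher and 12 were not called (28 higher adjusted over the list alone; median 0.56, adjusted p = 2.68e-12, and adjusted p = 0.386 with an estimated correlation), with Ndufv1 of complex I at 789 ± 113 against 488 ± 114 CPM (0.69 ± 0.16, adjusted p = 0.00875; adjusted p = 0.0503 without cKO TAC 3 d replicate 2). Of the fatty acid oxidation list 9 of 28 were higher and 19 were not called (19 higher adjusted over the list alone; median 0.68, adjusted p = 1.32e-09, and adjusted p = 0.386 with an estimated correlation), and Ppargc1a, a coactivator of mitochondrial genes, was at 137 ± 46.3 against 53.1 ± 19.3 CPM (1.37 ± 0.31, adjusted p = 0.00884). Without both libraries that lie apart, no member of either list was called by edgeR and the medians were 0.25 and 0.33. The number of oxidative phosphorylation genes called by edgeR was 2, 0, 6 and 2 without cKO TAC 3 d replicates 1 and 2 and ctrl TAC 3 d replicates 1 and 3, and that of fatty acid oxidation genes 2, 3 and 22 without cKO TAC 3 d replicate 2 and ctrl TAC 3 d replicates 3 and 2. Cardiac stress genes had a median of -0.81 (2 lower, 12 not called; 2 lower adjusted over the list alone; adjusted p = 0.0257, and not called with an estimated correlation). Without ctrl TAC 3 d replicate 3 or cKO TAC 3 d replicates 1 or 2 edgeR called 0 of them, with medians of -0.52, -0.48 and -0.75. Ventricular cardiomyocyte markers had a median of 0.54 (1 higher, 11 not called; 1 higher adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.386 with an estimated correlation). The median of all genes moved by -0.22 with library sizes in place of TMM, and 15.8% of the called genes were then higher, against 45.2% with TMM.

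Lists of amino acid genes held members called lower and members called higher in cKO at TAC 3 d. Not every member is raised by ATF4. Prodh, for one, was at 3.16 to 4.96 FPKM with adGFP and 1.15 to 2.81 FPKM with adATF4 in the rat cells. Prodh thus does not show an ATF4 target going the other way. The other members called higher were not set against the rat cells one by one. Whether ATF4 targets went both ways was not tested. Mthfd2, a mitochondrial folate enzyme, was at 2.65 ± 0.0839 against 8.35 ± 3.71 CPM (-1.65 ± 0.25, adjusted p = 0.00136) and Asns, asparagine synthetase, at 1.97 ± 0.234 against 5.08 ± 1.07 CPM (-1.35 ± 0.25, adjusted p = 0.00312). Aldh18a1 of proline synthesis was lower (-1.13 ± 0.22, adjusted p = 0.00445), and Prodh, which breaks proline down, was higher (1.61 ± 0.31, adjusted p = 0.00387). Of 20 cytosolic tRNA synthetases 5 were lower and 15 were not called (7 lower adjusted over the list alone; median -0.12, adjusted p = 0.0409, and adjusted p = 0.386 with an estimated correlation), led by Cars (14.2 ± 2.06 against 22.9 ± 0.411 CPM; -0.68 ± 0.10, adjusted p = 0.00136) and Aars (-0.54 ± 0.09, adjusted p = 0.00231). The serine, glycine and one-carbon list was not called (1 higher, 2 lower, 10 not called; 2 higher and 2 lower adjusted over the list alone; median -0.10, adjusted p = 0.705). Neither were other amino acid synthesis (3 higher, 4 lower, 7 not called; 7 higher and 4 lower adjusted over the list alone; median 0.28, adjusted p = 0.565) and amino acid transporters (1 higher, 1 lower, 9 not called; 1 and 1 adjusted over the list alone; median 0.06, adjusted p = 0.914).

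Among 30 antioxidant enzymes at TAC 3 d, 7 were higher in cKO, 1 was lower and 22 were not called (8 higher and 2 lower adjusted over the list alone). The list's median was 0.18 with TMM (adjusted p = 0.0319, and adjusted p = 0.386 with an estimated correlation) and -0.06 with library sizes. The median of all genes was 0.02 with TMM and -0.20 with library sizes. The sign of the list's median thus depends on the scaling, while the list stood above the median of all genes under both. Gstm1, a glutathione transferase, was at 166 ± 45.3 against 69.6 ± 25.6 CPM (1.26 ± 0.23, adjusted p = 0.00324) and Fth1, the ferritin heavy chain, at 1487 ± 329 against 885 ± 61.1 CPM (0.75 ± 0.14, adjusted p = 0.00397). Prdx4, the peroxiredoxin of the endoplasmic reticulum (ER), was at 14.3 ± 1.79 against 22.3 ± 3.35 CPM (-0.65 ± 0.14, adjusted p = 0.00697). Of 20 ER chaperones 8 were lower, 2 higher and 10 not called (8 and 2 adjusted over the list alone; median -0.22, adjusted p = 0.00141, and adjusted p = 0.386 with an estimated correlation), and the disulfide isomerase Pdia3 was at 128 ± 3.75 against 207 ± 26.9 CPM (-0.70 ± 0.10, adjusted p = 0.000915). Fmo2, a flavin monooxygenase, was at 65.4 ± 36.3 against 8.87 ± 1.58 CPM (2.88 ± 0.33, adjusted p = 0.000419) and Ppl, a cytoskeletal linker, at 9.19 ± 1.28 against 1.18 ± 0.915 CPM (2.96 ± 0.41, adjusted p = 0.000737). Of the 89 called genes named by the rule for cKO against ctrl at TAC 3 d, 47 kept their call with every library left out in turn. The call of 35 was lost without cKO TAC 3 d replicate 2.

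At TAC 7 d, cKO hearts had more RNA of the cardiac stress hormone Nppa, atrial natriuretic peptide, at 2731 ± 1250 against 316 ± 160 CPM (3.11 ± 0.60, adjusted p = 0.0435). Phlda3, a p53 target, was higher (56.4 ± 11.4 against 15.2 ± 1.93 CPM; 1.89 ± 0.25, adjusted p = 0.00423), and so was the amino acid transporter Slc38a1 (36.1 ± 4.50 against 13.0 ± 0.461 CPM; 1.47 ± 0.17, adjusted p = 0.00304). Kcnd2, a potassium channel of repolarization, was lower (5.07 ± 1.36 against 19.7 ± 2.61 CPM; -1.96 ± 0.32, adjusted p = 0.0180), as were Acot1, an acyl-CoA thioesterase (-1.95 ± 0.35, adjusted p = 0.0312), and the tRNA synthetases Cars (13.1 ± 0.982 against 22.9 ± 0.815 CPM; -0.81 ± 0.10, adjusted p = 0.00423) and Aars (-0.51 ± 0.09, adjusted p = 0.0312). edgeR called 40 genes, 18 higher and 22 lower, beside 2680 with an unadjusted p under 0.05. DESeq2 called 462. With no filter on low counts edgeR called 1149, and on the libraries of these 2 groups alone 10. The authors' deposited table gave 718 (374 higher, 344 lower). Without single libraries the count was 5 (cKO TAC 7 d replicate 2), 6, 9 and 21 (ctrl TAC 7 d replicates 2, 3 and 1), 12 (cKO TAC 7 d replicate 1) and 64 (cKO TAC 7 d replicate 3); of the 16 genes named by the rule, 4 (Atf4, Phlda3, Slc38a1 and Cars) were called each time, and Nppa had an adjusted p of 0.255 without ctrl TAC 7 d replicate 2.

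As a group, matrix genes were higher in cKO at TAC 7 d: 0 of 32 were called over all genes and 20 were higher adjusted over the list alone (median 1.19, adjusted p = 4.46e-19, and adjusted p = 0.320 with an estimated correlation). Fibroblast markers had a median of 0.63 (0 of 12 called; 5 higher adjusted over the list alone; adjusted p = 7.25e-06, and adjusted p = 0.229 with an estimated correlation) and cardiac stress genes one of 0.73 (1 higher, 13 not called; 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.000163, and adjusted p = 0.382 with an estimated correlation). Some markers of other cells moved the same way. Macrophage markers had a median of 0.51 (0 of 16 called, and 0 adjusted over the list alone; adjusted p = 7.87e-05, and adjusted p = 0.382 with an estimated correlation) and atrial cardiomyocyte markers, which include Nppa, one of 0.48 (1 higher, 5 not called; 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.229 with an estimated correlation). The 4 measured markers of epicardium and mesothelium had a median of 1.79 and were not called as a list (0 called over all genes; 2 higher adjusted over the list alone; adjusted p = 0.0691). Fatty acid oxidation genes had a median of -0.54 (0 of 28 called; 14 lower adjusted over the list alone; adjusted p = 3.23e-10, and adjusted p = 0.382 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.34 (0 of 30 called over all genes and 0 adjusted over the list alone; adjusted p = 4.77e-07, and adjusted p = 0.607 with an estimated correlation). Of the tRNA synthetases 2 of 20 were lower and 18 not called (5 lower adjusted over the list alone). The median was -0.10 (adjusted p = 0.000318, and adjusted p = 0.234 with an estimated correlation). The antioxidant list, with a median of 0.06, was not called. Without cKO TAC 7 d replicate 2, which lies apart, the medians were 0.99 for matrix genes, 0.40 for fibroblast markers, 0.37 for cardiac stress genes, 1.06 for epicardium and mesothelium, -0.43 for fatty acid oxidation and -0.25 for oxidative phosphorylation. Without ctrl TAC 7 d replicate 1 that of cardiac stress genes was 1.11.

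In ctrl hearts, 3 days of TAC raised matrix, proliferation, macrophage and cardiac stress genes and lowered energy genes. Tnc, the matrix protein tenascin C, rose from 1.13 ± 0.0861 to 79.5 ± 62.4 CPM (6.13 ± 0.73, adjusted p = 0.000153), Acta1, the skeletal actin of the fetal gene program, from 223 ± 59.5 to 2454 ± 1124 CPM (3.46 ± 0.44, adjusted p = 0.000234) and Nppa from 148 ± 27.2 to 1885 ± 1100 CPM (3.68 ± 0.62, adjusted p = 0.000786). Cyp26b1, which breaks down retinoic acid, fell from 69.1 ± 32.9 to 2.31 ± 1.42 CPM (-4.91 ± 0.70, adjusted p = 0.000318). Mthfd2 rose from 1.56 ± 0.0924 to 8.35 ± 3.71 CPM (2.42 ± 0.27, adjusted p = 0.000143), Asns by 1.36 ± 0.25 (adjusted p = 0.00131) and Atf4 itself by 0.60 ± 0.18 (adjusted p = 0.0219); Atf4 rose by 0.34 (adjusted p = 0.0460) without the library labelled ctrl sham replicate 3 and stood at 0.55 (adjusted p = 0.0598) without ctrl TAC 3 d replicate 1. Of the antioxidant enzymes 8 were higher, 8 lower and 14 not called (9 higher and 11 lower adjusted over the list alone; adjusted p = 0.805): Hmox1, heme oxygenase, rose from 7.33 ± 1.19 to 23.1 ± 11.0 CPM (1.66 ± 0.31, adjusted p = 0.00136) and Gstm1 fell by 1.20 ± 0.23 (adjusted p = 0.00187).

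The count for ctrl hearts at TAC 3 d was 4225 genes, 2305 higher and 1920 lower; it was 2310 without ctrl TAC 3 d replicate 3, 2769 and 2815 without ctrl sham replicates 1 and 2, and 2333 on the libraries of these 2 groups alone. All 32 matrix genes were higher (32 adjusted over the list alone). The median was 3.25 (adjusted p = 8.96e-28, and adjusted p = 0.168 with an estimated correlation). Cell cycle genes were higher for 24 of 25 with 1 not called (25 adjusted over the list alone). The median was 2.97 (adjusted p = 1.16e-24, and adjusted p = 0.168 with an estimated correlation). Macrophage markers were higher for 15 of 16 with 1 not called (15 adjusted over the list alone). The median was 1.61 (adjusted p = 1.72e-10, and adjusted p = 0.216 with an estimated correlation). Cardiac stress genes were higher for 11 of 14 with 3 not called (11 adjusted over the list alone). The median was 1.79 (adjusted p = 1.66e-07, and adjusted p = 0.168 with an estimated correlation). Oxidative phosphorylation genes were lower for 18 of 30 with 12 not called (24 lower adjusted over the list alone). The median was -0.58 (adjusted p = 7.57e-10, and adjusted p = 0.597 with an estimated correlation). Fatty acid oxidation genes were lower for 20 of 28 with 8 not called (23 lower adjusted over the list alone). The median was -0.84 (adjusted p = 5.45e-11, and adjusted p = 0.573 with an estimated correlation). The number lower was 10 for oxidative phosphorylation genes without ctrl TAC 3 d replicate 3 or ctrl sham replicates 1 or 2, and for fatty acid oxidation genes 13, 12 and 11 without these. With library sizes the median of all genes moved by 0.23. The authors' deposited table gave 3203 genes, 1890 higher and 1313 lower.

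In ctrl hearts at 7 days of TAC, part of the cardiac stress and matrix genes were called above sham, with counts that rest on single libraries, as given below. Acta1 was at 2455 ± 1047 against 223 ± 59.5 CPM (3.46 ± 0.44, adjusted p = 0.00127), Tnc at 19.8 ± 13.0 against 1.13 ± 0.0861 CPM (4.13 ± 0.72, adjusted p = 0.00688) and Hipk2, a stress-activated kinase, at 79.2 ± 38.6 against 7.49 ± 0.175 CPM (3.40 ± 0.37, adjusted p = 0.000299). Mthfd2 was at 4.84 ± 0.395 against 1.56 ± 0.0924 CPM (1.63 ± 0.27, adjusted p = 0.00567), and Cyp26b1 was lower (-3.53 ± 0.64, adjusted p = 0.00788). These 5 genes are among the 8 of the 60 called genes named by the rule that kept their call with every library left out in turn. The call of 50 was lost without ctrl sham replicate 1. Atf4 was at 0.38 and was not called (adjusted p = 0.201), and it was at 0.12 (adjusted p = 0.559) without the library labelled ctrl sham replicate 3. The count was 1132 genes, 662 higher and 470 lower. It was 87, 360 and 477 without ctrl sham replicates 1, 2 and 3, 222 and 374 without ctrl TAC 7 d replicates 1 and 2, 1715 with no filter on low counts, 2569 on the libraries of these 2 groups alone and 1733 by DESeq2; the authors' deposited table gave 2433 (1314 higher, 1119 lower). The fold changes followed gene length (Spearman correlation 0.23), and with the length trend of each library removed the count was 940, 499 higher and 441 lower.

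At 7 days in ctrl hearts 15 of 25 cell cycle genes were higher and 10 not called (22 higher adjusted over the list alone). The median was 1.79 (adjusted p = 7.71e-17, and adjusted p = 0.353 with an estimated correlation). Matrix genes were higher for 10 of 32 with 22 not called (16 higher adjusted over the list alone). The median was 1.11 (adjusted p = 1.59e-11, and adjusted p = 0.504 with an estimated correlation). Cardiac stress genes were higher for 8 of 14 with 6 not called (9 higher adjusted over the list alone). The median was 1.36 (adjusted p = 2.08e-08, and adjusted p = 0.319 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.32 with 1 of 30 lower (0 adjusted over the list alone; adjusted p = 3.60e-07, and adjusted p = 0.758 with an estimated correlation). With the length trend removed the medians of these lists were 1.75, 1.05, 1.32 and -0.26, and the members called 14, 9, 7 and 0. The member counts rest on single libraries. The cell cycle, matrix and cardiac stress genes called by edgeR were 0, 1 and 1 without ctrl sham replicate 1, 2, 4 and 3 without replicate 2, and 9, 4 and 2 without replicate 3. They were 2, 2 and 2 without ctrl TAC 7 d replicate 1, and 5, 5 and 6 without replicate 2. With each library left out in turn the medians ran from 1.57 to 2.17, 0.71 to 1.42 and 1.12 to 1.57.

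In cKO hearts, 3 days of TAC changed no single gene past the threshold: edgeR called 0 genes, beside 1311 with an unadjusted p under 0.05, and DESeq2 called 29. With no filter on low counts edgeR called 219. On simulated data with the spread of each gene over all 18 libraries, edgeR recovered 74.6% of genes changed 2-fold in this comparison. The simulation drew genes independently and held no library that lies apart, so the share found in these hearts may differ. Without cKO TAC 3 d replicate 1 it called 6 genes. The fold changes followed gene length (Spearman correlation -0.17), and with the length trend removed edgeR again called 0. Atf4 was at 0.12 (adjusted p = 0.898). Some lists moved as groups: matrix genes had a median of 0.51 (0 of 32 called; 3 higher adjusted over the list alone; adjusted p = 1.13e-08, and adjusted p = 0.516 with an estimated correlation), macrophage markers of 0.62 (0 of 16 called; 3 higher adjusted over the list alone; adjusted p = 3.73e-06, and adjusted p = 0.392 with an estimated correlation) and cardiac stress genes of 0.75 (0 of 14 called; 2 higher adjusted over the list alone; adjusted p = 5.62e-05, and adjusted p = 0.392 with an estimated correlation). Cell cycle genes, with a median of 0.22, were not called.

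After 7 days of TAC, cKO hearts showed a wide response. Tnc rose from 2.15 ± 0.269 to 44.2 ± 4.18 CPM (4.35 ± 0.66, adjusted p = 0.00134), Postn, the matrix protein periostin, from 40.9 ± 11.2 to 758 ± 431 CPM (4.21 ± 0.68, adjusted p = 0.00176) and Nppa from 360 ± 296 to 2731 ± 1250 CPM (2.92 ± 0.60, adjusted p = 0.00473). Ces1d, a lipid-hydrolysing carboxylesterase, fell from 125 ± 28.7 to 11.5 ± 5.27 CPM (-3.44 ± 0.61, adjusted p = 0.00241) and Cox7a1, a subunit of complex IV in muscle, from 634 ± 47.1 to 248 ± 60.5 CPM (-1.36 ± 0.27, adjusted p = 0.00445). Psat1 of serine synthesis (1.22 ± 0.27, adjusted p = 0.00648) and Mthfd2 (1.15, adjusted p = 0.0101) rose in these hearts too, although Atf4 was not called (0.28, adjusted p = 0.298). edgeR called 3380 genes, 1770 higher and 1610 lower; the count was 1353 without cKO TAC 7 d replicate 2, and 2018, 1849 and 1678 without cKO sham replicates 1, 2 and 3.

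Of the lists in cKO hearts at 7 days, 29 of 32 matrix genes were higher with 3 not called (31 higher adjusted over the list alone). The median was 2.24 (adjusted p = 9.39e-25, and adjusted p = 0.235 with an estimated correlation). Cell cycle genes were higher for 21 of 25 with 4 not called (23 higher adjusted over the list alone). The median was 1.91 (adjusted p = 1.54e-12, and adjusted p = 0.448 with an estimated correlation). Macrophage markers were higher for 12 of 16 with 4 not called (14 higher adjusted over the list alone). The median was 0.86 (adjusted p = 3.73e-07, and adjusted p = 0.448 with an estimated correlation). Oxidative phosphorylation genes were lower for 19 of 30 with 11 not called (30 lower adjusted over the list alone). The median was -0.55 (adjusted p = 3.14e-11, and adjusted p = 0.772 with an estimated correlation). Fatty acid oxidation genes were lower for 16 of 28 with 12 not called (19 lower adjusted over the list alone). The median was -0.73 (adjusted p = 2.21e-08, and adjusted p = 0.772 with an estimated correlation). With library sizes the median of all genes moved by 0.13. The fold changes followed gene length (Spearman correlation 0.20). With the length trend removed 3126 genes were called, and oxidative phosphorylation genes had a median of -0.45 with 9 of 30 lower. With each of cKO sham replicates 1 to 3 and cKO TAC 7 d replicates 1 and 2 left out in turn, 3 or 4 oxidative phosphorylation genes, 1 to 9 fatty acid oxidation genes and 1 to 6 macrophage markers were called. Without cKO TAC 7 d replicate 3 macrophage markers were 8, and without cKO sham replicate 3 cell cycle genes were 13.

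The genotype by TAC interaction tests whether the response to TAC differed between genotypes. At 3 days edgeR called 104 genes, 28 higher and 76 lower, beside 3290 with an unadjusted p under 0.05, and DESeq2 called 854. With no filter on low counts edgeR called 1597, and on the libraries of these 4 groups alone 0. Among the 104, mitotic genes rose less in cKO than in ctrl hearts, as for Bub1b (-3.08 ± 0.55, adjusted p = 0.0415) and Mki67, a proliferation marker (-3.55 ± 0.77, adjusted p = 0.0496), and so did Loxl2 (-2.09 ± 0.37, adjusted p = 0.0415). Ppl (3.13 ± 0.54, adjusted p = 0.0415) and Fmo2 (2.89 ± 0.44, adjusted p = 0.0415) went the other way. The difference for Atf4 was -0.47 (adjusted p = 0.297), and -0.21 (adjusted p = 0.443) without the library labelled ctrl sham replicate 3. Of 25 cell cycle genes 4 were lower (25 adjusted over the list alone; median -2.65, adjusted p = 4.41e-25, and adjusted p = 0.404 with an estimated correlation), of 32 matrix genes 3 were lower (28 adjusted over the list alone; median -2.24, adjusted p = 8.06e-24, and adjusted p = 0.404 with an estimated correlation), and of 30 oxidative phosphorylation genes none was called (19 higher adjusted over the list alone). The median was 0.66 (adjusted p = 3.91e-14, and adjusted p = 0.404 with an estimated correlation). Cardiac stress genes had a median of -1.10 (0 of 14 called; 3 lower adjusted over the list alone; adjusted p = 0.000353, and adjusted p = 0.404 with an estimated correlation). With library sizes the median of all genes moved by -0.26. The count was 1363 without ctrl TAC 3 d replicate 2, 489 without cKO TAC 3 d replicate 3, 1 without ctrl sham replicate 2, and 0 without any single one of ctrl sham replicates 1 and 3, cKO sham replicates 1 and 2, ctrl TAC 3 d replicates 1 and 3 or cKO TAC 3 d replicates 1 and 2, by edgeR.

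At 7 days the interaction called 0 genes by edgeR, and DESeq2 called 0. An unadjusted p under 0.05 was found for 682 genes. This is fewer than the share of 0.05 of the 15535 tested genes that no difference would give on average. The spread shared with the TAC 3 d groups may lower this count. With no filter on low counts edgeR called 96. Atf4 was at -0.11 (adjusted p = 0.951), and at 0.15 without the library labelled ctrl sham replicate 3. Matrix genes had a median of 0.97 (0 of 32 called, and 0 adjusted over the list alone; adjusted p = 2.61e-15, and adjusted p = 0.778 with an estimated correlation), fibroblast markers of 0.54 (0 of 12 called, and 0 adjusted over the list alone; adjusted p = 0.000395, and adjusted p = 0.673 with an estimated correlation) and fatty acid oxidation genes of -0.46 (0 of 28 called, and 0 adjusted over the list alone; adjusted p = 5.25e-07, and adjusted p = 0.778 with an estimated correlation).

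In rat myocytes, added ATF4 raised genes of amino acid synthesis, transport and tRNA charging. Slc7a3, a transporter of cationic amino acids, rose from 3.62 ± 0.690 to 301 ± 12.7 FPKM (6.04 ± 0.12, adjusted p = 2.17e-09), Cth, which makes cysteine, from 3.19 ± 0.609 to 141 ± 11.7 FPKM (5.09 ± 0.13, adjusted p = 4.64e-09), Phgdh, the first enzyme of serine synthesis, from 44.0 ± 3.23 to 356 ± 39.9 FPKM (2.99 ± 0.10, adjusted p = 1.89e-08) and Asns from 32.7 ± 2.63 to 235 ± 2.45 FPKM (2.81 ± 0.09, adjusted p = 1.25e-08). Gulo, an enzyme of vitamin C synthesis, rose from 0.177 ± 0.143 to 107 ± 10.2 FPKM (6.53 ± 0.15, adjusted p = 2.17e-09); C1ql2 and Wfdc12 stood at 98.7 ± 13.9 and 64.8 ± 5.35 FPKM and were listed at 0 in all adGFP libraries. Of the 10571 genes tested, 5348 were called, 2561 higher and 2787 lower.

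Of 20 tRNA synthetases 19 were higher with adATF4 and 1 was not called (19 adjusted over the list alone). The median was 1.69 (adjusted p = 6.30e-13, and adjusted p = 0.0845 with an estimated correlation). Serine, glycine and one-carbon genes were higher for 9 of 12 with 3 not called (9 adjusted over the list alone). The median was 2.15 (adjusted p = 7.87e-07, and adjusted p = 0.0845 with an estimated correlation). Amino acid transporters were higher for 10 of 13 with 3 not called (10 adjusted over the list alone; median 1.91, adjusted p = 3.75e-07, and adjusted p = 0.0845 with an estimated correlation) and regulators of the ATF4 stress response for 15 of 18 with 3 not called (15 adjusted over the list alone; median 1.48, adjusted p = 2.30e-09, and adjusted p = 0.105 with an estimated correlation), such as Atf3 at 90.0 ± 3.12 against 5.73 ± 0.484 FPKM (3.76 ± 0.11, adjusted p = 7.46e-09). Interferon response genes were higher for 16 of 18 with 2 not called (17 adjusted over the list alone). The median was 1.17 (adjusted p = 3.25e-06, and adjusted p = 0.313 with an estimated correlation).

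Antioxidant enzymes split in the rat cells: 14 were higher, 10 lower and 6 not called, and the list was not called (14 higher and 10 lower adjusted over the list alone; median 0.26, adjusted p = 0.371). Prdx3, the mitochondrial peroxiredoxin, rose from 137 ± 5.10 to 340 ± 9.21 FPKM (1.30 ± 0.08, adjusted p = 7.55e-07), Hmox1 from 27.96 ± 4.02 to 87.3 ± 7.84 FPKM (1.61 ± 0.12, adjusted p = 3.70e-06) and Srxn1, sulfiredoxin, by 1.36 ± 0.11 (adjusted p = 4.74e-06). Of the pentose phosphate and NADPH list 9 were higher, 7 lower and 2 not called (10 higher and 7 lower adjusted over the list alone; adjusted p = 0.360). Idh2, a mitochondrial source of NADPH, fell from 659 ± 12.6 to 316 ± 18.0 FPKM (-1.06 ± 0.08, adjusted p = 4.27e-06).

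Most fatty acid oxidation and matrix genes, and part of the calcium handling genes and ventricular markers, fell with adATF4 in the rat cells. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 910 ± 53.4 to 291 ± 4.99 FPKM (-1.64 ± 0.08, adjusted p = 2.31e-07) and Myom2, an M-band protein, from 562 ± 49.6 to 66.0 ± 3.95 FPKM (-3.07 ± 0.09, adjusted p = 9.52e-09), while Acta1 rose from 176 ± 5.98 to 1836 ± 362 FPKM (3.36 ± 0.13, adjusted p = 3.12e-08). Fatty acid oxidation genes were lower for 20 of 27, with 1 higher and 6 not called (20 lower and 1 higher adjusted over the list alone). The median was -0.76 (adjusted p = 1.87e-06, and adjusted p = 0.0845 with an estimated correlation). Oxidative phosphorylation genes were lower for 19 of 30, with 1 higher and 10 not called (20 lower and 1 higher adjusted over the list alone). The median was -0.33 (adjusted p = 0.000393, and adjusted p = 0.311 with an estimated correlation). Calcium handling genes were lower for 10 of 17, with 1 higher and 6 not called (10 lower and 1 higher adjusted over the list alone). The median was -0.49 (adjusted p = 0.00345, and adjusted p = 0.196 with an estimated correlation). Ventricular markers were lower for 6 of 11 with 5 not called (6 lower adjusted over the list alone). The median was -0.55 (adjusted p = 0.00334, and adjusted p = 0.139 with an estimated correlation). Matrix genes were lower for 22 of 28, with 2 higher and 4 not called (24 lower and 2 higher adjusted over the list alone). The median was -1.01 (adjusted p = 1.00e-07, and adjusted p = 0.0845 with an estimated correlation). Fibroblast markers were lower for 8 of 10 with 2 not called (9 lower adjusted over the list alone). The median was -1.36 (adjusted p = 0.000393, and adjusted p = 0.0845 with an estimated correlation).

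Whether genes moved by added ATF4 in rat cells move the other way in cKO hearts was tested with the 818 genes called at least 2-fold higher and the 803 called at least 2-fold lower with adATF4. Of the raised set 640 were measured in mouse; at TAC 3 d 34 of them were higher and 89 lower in cKO, and their median was -0.08 against 0.00 for the other shared genes. This was not called over the 6 tests (adjusted p = 0.126, and adjusted p = 0.150 with an estimated correlation). The lowered set, with 710 genes measured, was not called at TAC 3 d (107 higher, 129 lower; adjusted p = 0.861), and neither set was called in sham hearts (adjusted p = 0.658 for both) or at TAC 7 d (adjusted p = 0.658 for the raised and 0.454 for the lowered set).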

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

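All tests of explanations in this part, the contrast of 7 d with 3 d, and the counts of other splits of the samples were chosen or set out only after the results were seen; the 2 interaction contrasts were written before the data were examined. The test of a cardiomyocyte share is a second version, rewritten after the value of the first was seen.

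The genotype by TAC interaction at 3 days called 104 genes by edgeR (3290 at an unadjusted p under 0.05, and 854 by DESeq2) and 13 lists, in a test of whether the difference between cKO and ctrl hearts was itself larger or smaller at TAC 3 d than in sham hearts. Chance cannot be excluded as the source of either count: of 100 drawn splits, 7 gave as many genes, with up to 702 in a split other than the real one, and 25 gave as many lists, with up to 17. All 7, the real one included, kept cKO and ctrl libraries apart at TAC 3 d, and the 91 splits that mixed them there gave at most 5 genes. Of the 8 other splits that kept them apart, 6 gave as many genes as the real one. The high counts thus go with the genotype groups at TAC 3 d, mostly under other splits of the sham libraries too, so the count of genes does not by itself show a difference from sham hearts. Without ctrl TAC 3 d replicate 3 the interaction called 0 genes by edgeR.

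The interaction at 7 days called 0 genes by edgeR (682 at an unadjusted p under 0.05, and 0 by DESeq2) and 7 lists, led by the extracellular matrix list at a median of 0.97. The 682 are fewer than no difference would give on average among the 15535 genes tested. Of 100 drawn splits, 69 gave as many lists, with up to 18, so chance is not excluded for the lists. For genes the splits decide nothing, since any split gives at least 0: all 100 gave as many, with 1 as the highest of the others.

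The difference between cKO and ctrl hearts changed between 3 and 7 days of TAC. For cell cycle genes it was near 0 at 7 d (median -0.07, against -2.91 at 3 d). For matrix genes the median went from -2.06 to 1.19, but 0 of 32 were called at 7 d by edgeR (20 higher adjusted over the list alone), so a change of sign is not shown for single genes over all genes. The contrast of the genotype effect at 7 d with that at 3 d, added after seeing the data, called 3266 genes, 1713 higher and 1553 lower, and 13 lists. Matrix genes stood higher in cKO relative to ctrl at 7 d than at 3 d for 31 of 32 members (31 adjusted over the list alone; median 3.52, adjusted p = 8.31e-29, and adjusted p = 0.458 with an estimated correlation), and cell cycle genes for 23 of 25 (23 adjusted over the list alone; median 3.00, adjusted p = 2.85e-17, and adjusted p = 0.458 with an estimated correlation). Fatty acid oxidation genes stood lower for 20 of 28 (25 adjusted over the list alone; median -1.25, adjusted p = 7.17e-14, and adjusted p = 0.458 with an estimated correlation) and oxidative phosphorylation genes for 24 of 30 (30 adjusted over the list alone; median -0.84, adjusted p = 6.49e-14, and adjusted p = 0.472 with an estimated correlation). Nppa (4.48 ± 0.82, adjusted p = 0.00493), Loxl2 (2.87 ± 0.37, adjusted p = 0.00380) and Bub1b (2.61 ± 0.50, adjusted p = 0.00540) were among the genes that moved, and Atf4 was not called (0.37, adjusted p = 0.318). Of 100 drawn splits, 1, the real one, gave as many genes, with 2551 in the highest of the others. Only 1 other split kept the genotypes apart at both days, and it gave 228 genes. Splits that mix the genotypes remove the genotype effect itself, so this count cannot exclude chance for a change between the days. The split with 2551 genes kept the genotypes apart at TAC 3 d and mixed them at 7 d, so much of the real count can come from the difference at 3 d. Of the splits 29 gave as many lists, with up to 17, so chance is not excluded for the lists. The count was 2069 without ctrl TAC 3 d replicate 3, 1758 and 2058 without ctrl TAC 7 d replicates 2 and 3, and 2001 without cKO TAC 7 d replicate 2. With library sizes the median of all genes moved by 0.32.

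Cell cycle and matrix genes were lower in cKO than in ctrl hearts at TAC 3 d. The 2 libraries that lie apart are argued against as the whole cause: without ctrl TAC 3 d replicate 3 and cKO TAC 3 d replicate 2 the medians were -2.63 for cell cycle and -1.50 for matrix genes. The scaling is argued against as well, since with library sizes they were -3.12 and -2.36, and so is a trend with gene length, since with it removed they were -2.90 and -2.05. A larger share of cardiomyocyte RNA in cKO, acting alone, would lower the markers of all other cells alike. Macrophage markers stood -0.93 from endothelial markers (95% interval over 16 and 12 marker genes -1.60 to -0.59). The interval treats genes of the same hearts as independent, so it does not measure the spread between hearts. It cannot exclude a larger cardiomyocyte share beside a fall of macrophage RNA. The shift rests in large part on ctrl TAC 3 d replicate 3: without that library it was -0.25 (-0.60 to -0.01), and without both libraries -0.31 (-0.66 to -0.11). A constriction that was tighter in some animals than in others, an earlier or later response, and an effect of ATF4 on these cells all may hold, and were not tested.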

How the results depend on the processing

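The removal of libraries together, library sizes without scaling factors, and offsets for gene length were chosen only after the results were seen; the other settings were written before. Over 6796 settings for single named genes, 5649 kept direction and call, 1145 kept the direction and lost the call, and 2 turned over. Of 518 for counts, lists and sets, 429 were rated unchanged and 89 moved. Counts of genes and lists were rated unchanged within 1.5 times the value reported, and levels of Atf4 within their SD. Sets from rat cells were rated by their call alone. A set that stayed not called thus adds to the 429, whatever its p-value. The 2 that turned over are the difference of Atf4 in the interaction at 7 d, which is -0.11 and was 0.15 both without ctrl sham replicate 3 and without it and ctrl TAC 3 d replicate 3 (-0.27 to 0.15 with each library left out). With an estimated correlation 0 lists were called in every comparison. Except where stated, the cause of a change was not tested. A left-out library leaves fewer samples in the test.

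With no filter on low counts, the genes called were 67 in sham hearts, 1149 for cKO against ctrl at TAC 7 d, 1715 for TAC 7 d in ctrl, 219 for TAC 3 d in cKO, 1597 for the interaction at 3 d and 96 for that at 7 d, and 17 lists were called for TAC 3 d in ctrl. DESeq2 called 16, 462, 1733 and 29 genes in the first 4 of these and 854 for the interaction at 3 d. The replicate number as a block gave 0 genes by edgeR in sham hearts and 24 for cKO against ctrl at TAC 7 d. Whether replicate numbers pair the libraries is not settled here. Deviations of same-numbered libraries from their group means correlated at -0.16 to 0.18 in the mouse comparisons of 2 groups. In the rat cells they correlated at -0.06 to 0.22. Only the libraries of the groups compared gave 31 genes in sham hearts, 114 and 10 for cKO against ctrl at TAC 3 d and 7 d, 2333 and 2569 for TAC 3 d and 7 d in ctrl, 0 for the interaction at 3 d by edgeR and 1316 for 7 d against 3 d. A fold of at least 1.5, which can only lower a count, left 710 genes for TAC 7 d in ctrl and 2143 for TAC 7 d in cKO. Library sizes gave 285 genes for the interaction at 3 d, and Atf4 at 24.2 CPM in cKO and 94.4 CPM in ctrl at TAC 3 d. With them the share of called genes that were higher was 15.8% (45.2% with TMM) for cKO against ctrl at TAC 3 d, 82.4% (54.6%) and 75.3% (58.5%) for TAC 3 d and 7 d in ctrl, and 71.6% (52.4%) for TAC 7 d in cKO.

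Without ctrl TAC 3 d replicate 3 and cKO TAC 3 d replicate 2, the genes called were 450 for cKO against ctrl at TAC 3 d, 2584 for TAC 3 d in ctrl, 0 for the interaction at 3 d and 1661 for 7 d against 3 d. Without ctrl sham replicate 3 and ctrl TAC 3 d replicate 3 they were 913, 1585, 0 and 1794. With each library left out in turn the genes called ran from 0 to 2 in sham hearts, 953 to 3853 for cKO against ctrl at TAC 3 d, 5 to 64 at TAC 7 d, 2310 to 4936 and 87 to 883 for TAC 3 d and 7 d in ctrl, 0 to 6 and 1353 to 2900 for TAC 3 d and 7 d in cKO, 0 to 1363 for the interaction at 3 d and 1758 to 4465 for 7 d against 3 d, and lists from 3 to 8 in sham hearts and 6 to 11 for the interaction at 7 d. Where edgeR called 0 it gave 565 genes in sham hearts, 1311 for TAC 3 d in cKO and 3290 for the interaction at 3 d at an unadjusted p under 0.05 with all libraries. The 565 in sham hearts are fewer than no difference would give on average among the 15535 genes tested. The spread shared with the TAC groups may lower that number.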

Other observations

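All tests of explanations in this part, and the counts of other splits of the samples, were chosen or set out only after the results were seen; the gene lists were fixed before the data were examined.

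Some clock genes were lower at TAC 3 d than after sham surgery in ctrl hearts. At TAC 3 d 8 of 16 circadian genes were lower and 8 not called (8 lower and 1 higher adjusted over the list alone; median -0.78, adjusted p = 0.00232, and adjusted p = 0.168 with an estimated correlation), among them Tef, a clock output factor, at 144 ± 15.3 against 272 ± 6.32 CPM (-0.92 ± 0.18 SE, adjusted p = 0.00177), and Cry2, a clock repressor, at 33.8 ± 4.36 against 58.7 ± 5.81 CPM (-0.79 ± 0.14, adjusted p = 0.000954). In cKO hearts at TAC 7 d 6 were lower, 3 higher and 7 not called (7 lower and 3 higher adjusted over the list alone; median -0.64, adjusted p = 0.0134, and adjusted p = 0.235 with an estimated correlation). Between the genotypes at TAC 3 d, Per2 stood at 46.6 ± 1.43 CPM in cKO and 19.4 ± 1.41 CPM in ctrl hearts (1.27 ± 0.25, adjusted p = 0.00427). The time of day at which hearts were taken is not given in the sources used here.

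Markers of nerve and Schwann cells were lower in ctrl hearts at TAC 7 d for 3 of 8 genes, with 5 not called (3 adjusted over the list alone; median -0.66, adjusted p = 0.0210, and adjusted p = 0.504 with an estimated correlation). With each library left out in turn, 0 to 2 were called by edgeR (0 without ctrl sham replicates 1 or 2 or ctrl TAC 7 d replicate 2). Among them were Sox10, a Schwann cell factor (0.828 ± 0.512 against 3.59 ± 0.935 CPM; -2.09 ± 0.51, adjusted p = 0.0244), and Dbh, the enzyme that makes noradrenaline (-1.74 ± 0.46, adjusted p = 0.0336). Both lost their call without at least 1 library: Sox10 had an adjusted p of 0.0972 without ctrl TAC 7 d replicate 2, and Dbh one of 0.150 without ctrl sham replicate 1.

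The library labelled ctrl sham replicate 3 had Cacna1i near the level of cKO hearts (24.6 CPM) and Atf4 at 50.8% of the mean of the other ctrl sham libraries. Rps19bp1 was at 3.04 CPM, against 2.43 to 3.04 CPM in cKO sham and 6.35 and 8.39 CPM in the other ctrl sham libraries. Labels swapped with a cKO sham library are argued against: the lowest Cacna1i level among libraries labelled cKO sham was 26.9 CPM, and the highest in the other ctrl libraries 0.256 CPM. For a cKO heart under a ctrl label, 34 genes other than these were chosen by their differences between the TAC libraries. Their mean score was 1.15 in this library and 1.08 and 1.14 in the other ctrl sham libraries. It was at least 1.75 in the cKO sham libraries. The spread used in the choice came from all 18 libraries, this one included. Genes in which this library resembled cKO were thus less likely to be chosen. On these genes the library stood with ctrl, but the score cannot exclude a cKO heart. With RNA of a cKO heart mixed in, the same score would be 1.73 at the share of 88.2% that Cacna1i needs. The same limit holds for this comparison. One altered copy of Atf4 that acts on its own chromosome alone would put these genes midway between ctrl and cKO hearts, and Atf4 stood at 75.5% and Cacna1i at 88.2% of the way. What sets this library apart stays open, and no genotype is given for single animals.

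Cacna1i was higher and Rps19bp1 lower in cKO hearts, and both lie near Atf4. Reads of the Atf4 transcript counted to Rps19bp1 cannot be told apart from a fall of Rps19bp1 itself: the ratio of their counts lay inside the range of the ctrl libraries in 5 of the 9 cKO libraries and outside it in the other 4. An effect of the ATF4 protein on Rps19bp1 cannot be told apart from one of the altered locus, since in rat myocytes, where ATF4 was added and not removed, Rps19bp1 stood at -0.10 (adjusted p = 0.613). That transcription runs on from the altered Atf4 locus into Cacna1i may also hold; reads along the region were not analysed here.

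With 3 libraries against 3 there are 10 splits of the samples, too few for a share under 0.05. For genes called, the real split and the highest of the others gave 3 and 0 in cKO against ctrl sham hearts, 2655 and 5 at TAC 3 d, 40 and 0 at TAC 7 d, 4225 and 0 for TAC 3 d against sham in ctrl, 1132 and 0 for TAC 7 d in ctrl, 3380 and 1 for TAC 7 d in cKO, and 5348 and 0 for adATF4 against adGFP; in each of these 1 split of the 10, the real one, gave as many. For TAC 3 d against sham in cKO the real split gave 0 by edgeR (1311 at an unadjusted p under 0.05, 29 by DESeq2) and the highest of the others 4; all 10 gave as many, as any split must with a real count of 0. For lists called, in the same order of the cKO against ctrl comparisons, they gave 8 and 9 (2 splits with as many), 13 and 13 (2 splits) and 14 and 16 (4 splits). For TAC against sham they gave 11 and 15 at 3 d (7 splits) and 11 and 11 at 7 d (2 splits) in ctrl, and 10 and 14 (2 splits) and 8 and 11 (7 splits) in cKO; adATF4 against adGFP gave 21 and 13 (1 split). For the sets from rat cells, the unadjusted p of the raised set and the smallest p of the other splits were 0.488 and 0.323 in sham hearts (3 splits with a p as small), 0.0210 and 0.0483 at TAC 3 d (1 split) and 0.548 and 0.239 at TAC 7 d (5 splits). Those of the lowered set were 0.401 and 0.0770 (10 splits), 0.861 and 0.0543 (7 splits) and 0.151 and 0.0150 (3 splits).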
